A study of Gallus gallus with 44 samples.

How the data were processed

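The measurements are 2-colour microarrays of liver RNA from 44 birds and the birds' genotypes at 32 microsatellite markers. Per the labels, RNA was extracted with TRIzol, and 5 µg were labelled with Cy5 for the bird and with Cy3 for the reference pool, so every ratio here is bird over reference. Per the file headers, the deposited spot tables give the foreground and background intensity of each spot in both channels, with flags, on a linear scale and without normalization. The scanner software is not given in the sources used here. The authors' deposited table holds log2 values for 44 birds and 7143 probes with values for all birds. Its scale was found by setting each column against the spot tables: with no background subtraction the columns correlated with their own arrays at a median of 0.98 and a slope of 1, so its direction is bird over reference, while the centring, and how the authors treated dim spots, stay unknown. Column medians lay between -0.081 and 0.161. The own array correlated best for 41 of 43 birds. For birds 4145 and 5670 the correlation was 0.52 and 0.62. The correlations so far were taken over the tested probes in both sources, with each probe's mean removed. Without that removal, over the authors' probes, these birds had correlations of 0.99 and 0.96 for the usable spots. For the other spots these were 0.09 and 0.49.

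The arrays held 21120 spots in 48 print blocks, of which 660 were control or buffer spots and 20460 were probes, 1 spot each. Background was corrected with normexp (offset 50) and each array was normalized with loess in limma 3.58.1 under R 4.3.3, with control and flagged spots at weight 0. A spot counted as usable if it was not flagged and its foreground exceeded the background by more than 2 SD in either channel. Flagged spots made up a median of 49.7% of an array (13.6 to 72.4%). Probes usable on at least 75% of the arrays were tested, 5763 in all, of which 5218 are also in the authors' table. A dim spot on a tested probe kept its normalized value. The median foreground of the bird channel was 259 and its median background 228, so most probes lay near background. Correlations between arrays lay between -0.18 and 0.69 over all probes and between -0.28 and 0.85 over the tested probes, and none were so alike as to be duplicates.

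The sire's alleles at a marker were taken to be those that the birds' labels list first. A marker was informative where there were 2 of them. The paternal allele of birds that carried both was taken from a hidden Markov model over neighbouring markers (Python 3.11.15, numpy 2.4.6), with maternal allele frequencies estimated by expectation-maximization and a genotyping error of 0.01. Where a bird carried both sire alleles, the order in which its label lists them was not taken as paternal first. Over 11 tightly linked marker pairs this order gave 76 recombinants in 220 comparisons (34.5%) where a bird's own genotype left the allele open. It gave 6 in 195 (3.1%) where the genotype did not. The pairs were chosen for low estimated recombination, which rests largely on these settled genotypes, so a low share there follows from the choice. In 20 simulated families, 88.8% of the alleles were settled with a probability above 0.9 and 99.0% of those were right. These families were drawn from the model's own marker order, sire alleles, recombination and maternal frequencies, without genotyping errors. The simulation therefore cannot test those settings. The markers were taken in the order of the labels, where lei0079 of block C stands between mcw0181 and mcw0020 of block D, which were tightly linked (lod 5.79). Linkage blocks were fixed from the labels by 2-point lod scores.

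Each probe was regressed on the probability of the higher-numbered sire allele at each marker with limma's lmFit and eBayes. The p-values were adjusted by Benjamini-Hochberg over all probes and all 29 markers, or, for 1 index marker per block, over its probes alone, with a threshold of 0.05, two-sided. The design named 44 birds, and 43 entered because 1 spot table was not used here. The scan was tested on simulated data made from the arrays with birds reassigned and 200 probes changed in each of 10 runs; besides the changed probes a run called between 0 and 89 others, with a median of 2. Intervals of the SD come from 1000 bootstrap draws of birds.

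Before the data were examined, the rule for naming genes was fixed: the 30 genes with the smallest adjusted p, 5 per block, up to 4 per gene list, the 25 of largest SD, and markers of other cell types. It applied only to probes with 1 gene name, and no file used here gave one, since none of the probe identifiers matched the reference table of the GRCg7b assembly. The 25 fixed gene lists, their co-variation, the chromosomes of linked genes and the averaging of probes per gene were therefore not analysed here. The slide and scan date are not given in the files used here, so the planned batch term was not run. Alternatives covered background correction, normalization, the authors' values, the filter on dim probes, the way paternal alleles were assigned, covariates, the bird with the other reference label, and ranks in place of ratios. Outlying samples were not tested, because the only group has more than 10 birds.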

Results

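Liver RNA of 44 male chickens was profiled on 2-colour arrays, 1 array per bird. All birds were labelled BC2, were sons of sire 1998 and so half-brothers or closer, and were sampled at 9 weeks of age after at least 4 h of free access to feed. Each array set the RNA of 1 bird, labelled with Cy5, against a reference pool of liver RNA labelled with Cy3. The labels of 43 birds give this pool as 45 males of the same sire, and the label of bird 4145 gives 48 males of sire 1940. The birds form a single group, and what separates them in the labels is their genotype at 32 microsatellite markers. The series was made for the detection of expression quantitative trait loci, that is, of chromosome regions where the allele a bird received goes with the amount of a transcript. The comparison is therefore between sons that received one allele of the sire and sons that received the other. Spot tables were used for 43 of the birds, and bird 5699 was available only in the authors' table of processed values.

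Each array held 20460 probes, and 5763 of them (28.2%) were bright enough on enough arrays to be tested. On the median array 35.2% of the spots were usable, with a range of 20.3 to 67.1%, and 2201 probes were usable on all 43 arrays. The number of arrays limits the precision of every value below. The files used here do not pair the probe identifiers with gene names or positions, so probes are given by identifier, and were not grouped by pathway.

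Going by the alleles listed first in the labels, the sire carried 2 different alleles at 29 of the 32 markers. These were placed in 9 linkage blocks, A to I. The blocks are working units and were not all shown to be separate: lod scores between blocks reached 2.77 (mcw0083 in E with mcw0150 in F) and 2.75 (lei0032 in F with mcw0178 in I), above the 1.70 that joins adl0328 to seq0291 within block D and the 2.23 of the pair in block B. Of the 1276 combinations of bird and informative marker, 1150 were typed, and in 384 the bird carried both sire alleles, so that its own genotype left the paternal allele open. With the neighbouring markers taken into account, the model gave a paternal allele with a probability above 0.9 for 88.2% of the combinations. The sire's alleles were passed on in proportions that did not differ from equal at any of the 29 markers. The smallest exact binomial p, two-sided, was 0.174 at adl0313, where 27 birds carried one allele and 17 the other, and its adjusted p was 1.

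A single probe passed the threshold, and not under every processing. This probe, RIGG01025, had a mean log2 intensity of 8.8 and was usable on all 43 arrays. It was lower in the livers of sons that received allele 5 of marker huj0006, in block F, than in those that received allele 1. Its log2 ratio to the reference pool was 0.10 ± 0.19 (SD, n = 24) with allele 1 and -0.30 ± 0.23 (SD, n = 15) with allele 5. The fitted difference was -0.40 (95% confidence interval -0.54 to -0.26), a 1.32-fold lower level. All 24 birds with allele 1 lay above the mean of the birds with allele 5. These means and counts cover the 39 birds whose allele was settled with a probability above 0.9. The fitted difference used all 43 birds. Among the unsettled birds, bird 5696, with a probability of 0.24 for allele 5, lay below the allele 5 mean at -0.38. The limma p was 4.72e-07, and after Benjamini-Hochberg adjustment over all probes and all 29 markers it was 0.0419, just under the threshold of 0.05. Over the probes at huj0006 alone the adjusted p was 0.00272. The neighbouring marker mcw0150 separated the birds in the same way, and the other markers of the block, lei0032 and lei0161, gave differences of 0.37 in size with an adjusted p of 0.125 over all markers.

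**Figure D1:**
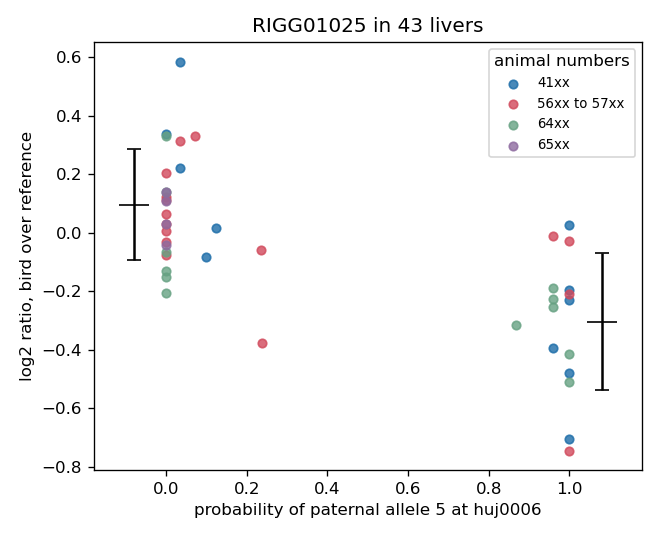
Log2 ratio of probe RIGG01025 (y axis, bird over reference pool) in each of 43 livers against the probability that the bird received allele 5 of huj0006 from its sire (x axis), coloured by the series of animal numbers. Black marks give the mean ± SD of the 24 birds with allele 1 (left) and the 15 birds with allele 5 (right), at 0.10 and -0.30.

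The difference was of the same sign in each series of animal numbers that held both alleles. It was -0.60 (SE 0.16) among the 11 birds numbered 41xx, -0.35 (SE 0.13) among the 16 birds numbered 56xx to 57xx, and -0.32 (SE 0.10) among the 12 birds numbered 64xx, while the 4 birds numbered 65xx all carried allele 1. With the series as a covariate the difference was -0.41 and the adjusted p rose to 0.146. The adjusted p also passed 0.05 with no background correction (0.104), no filter on dim probes (0.111), a genotyping error of 0.05 (0.0562), own genotypes only (0.860), inverse normal ranks (0.859) and the first listed allele taken as paternal (1.00). Own genotypes alone settled the allele of only 30 birds at huj0006. Leaving out 1 bird at a time ended the call for 30 of the 43 birds, with adjusted p between 0.0134 and 0.146, while the difference stayed between -0.43 and -0.37.

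No probe passed the threshold in the other 8 blocks. In block D, the block with the smallest p outside block F, the lowest was 2.89e-05 at mcw0020, for a difference of -0.34 (SE 0.07), and its adjusted p was 0.966. The smallest adjusted p was 1.00 in each of blocks A, B, C, E, G, H and I. Adjusting over the probes of 1 marker at a time, as 1 comparison per block, gave 1 probe at huj0006, lower with allele 5, and 0 probes at the other 8 index markers with limma. When genotypes were reassigned among birds, 22 of 100 draws, the real one included, gave 1 or more probes at an index marker. At an unadjusted p under 0.05 there were 322 probes at huj0006, 231 at lei0217 (block A), 96 at adl0313 (block B), 284 at lei0106 (block C), 236 at seq0291 (block D), 253 at mcw0083 (block E), 55 at mcw0238 (block G), 116 at lei0064 (block H) and 93 at seq0296 (block I), out of 5763. The share of probes with such small values over all 29 markers was highest at mcw0020, where it was 10.9%, and lowest at mcw0238, where it was 1.0%. When the genotypes were reassigned among the birds, the 95th percentile of this share was 12.5% at mcw0020, so no marker exceeded the range that reassigned birds gave.

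**Figure D2:**
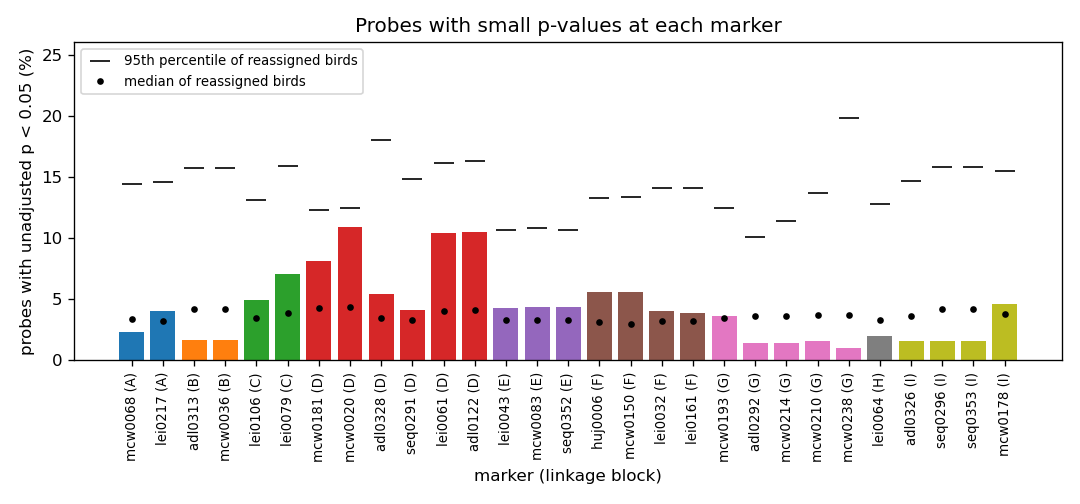
Percentage of the 5763 probes with an unadjusted p under 0.05 (y axis) at each of the 29 markers (x axis, with the linkage block and its colour). Bars are the observed shares, dots the median and dashes the 95th percentile after the genotypes were reassigned among birds; every bar lies below its dash, with 10.9% against 12.5% at mcw0020.

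The precision of these comparisons depended on the spread between birds and on how far the paternal alleles were settled. The allele was settled with a probability above 0.9 for 44 genotyped birds at lei0217 and for 34 at mcw0083. The median probe had a 95% confidence half-width of 0.14 log2 units at lei0217 and of 0.16 at mcw0083, the narrowest and widest of the 9 index markers. At huj0006 the interval lay within 0.5 log2 units of 0 for 97.7% of the probes. In simulated data with the same birds, a paternal difference of 0.3 log2 units was recovered for 41.5% of the changed probes, 0.4 for 74.0% and 0.6 for 93.5%. These simulations changed 200 probes at a time, which makes the adjusted threshold easier to pass than when few probes differ.

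The spread of the log2 ratios between half-brothers of the same age and sex was small for most probes and large for a few. With 1 array per bird it includes the error of the array, which was not measured separately. The SD over birds was 0.23 log2 units for the median probe (95% bootstrap interval 0.21 to 0.24), 0.14 at the 5th percentile of probes and 0.44 at the 95th. It exceeded 0.5 for 183 probes and 1 for 6 probes. The most variable, RIGG02581, had an SD of 1.38 (95% bootstrap interval 1.22 to 1.47) and ranged from -3.11 in one bird to 0.90 in another, a 16.1-fold range. It was singled out after its values were seen. Among the 25 most variable probes the smallest unadjusted p at any of the 29 markers was 0.00553, and none passed the adjusted threshold.

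A large share of this variation lay along 1 axis, and the share was smaller in the authors' values than in those used here. The first principal component over the birds held 31.9% of the variance of the tested probes, the next 12.2% and 7.8%, against at most 3.2% for the first component when each probe's values were shuffled among birds. In the authors' table, with 7143 probes and 44 birds, the first component held 16.03%. Over the 5218 probes and 43 birds shared with the values used here it held 25.97%, against 31.5% in the values used here. Without birds 4145 and 5670 these shares were 28.6% and 32.15%. Of the 5763 tested probes, 481 followed the first component of the values used here with a correlation above 0.8 in size, and 462 of these had the same sign. Of the 25 most variable probes, 24 had loadings of one sign. These loadings include the probes themselves and are no test.

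**Figure D3:**
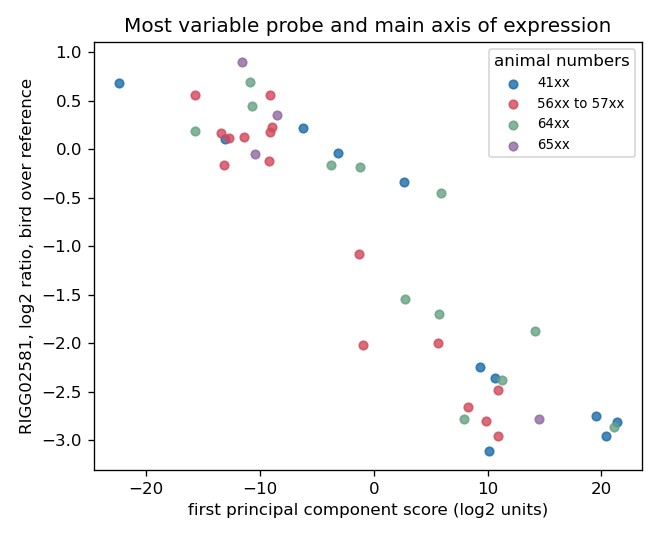
Log2 ratio of RIGG02581 (y axis, bird over reference pool) against the score of each of 43 birds on the first principal component (x axis), coloured by the series of animal numbers. The birds range from -3.11 to 0.90, and low values go with high scores in every series.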

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

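The 2 settings that combine 5 principal components with other values were chosen after seeing the data. The count of linked probes over all markers, 1 in the main setting, was also 1 with an offset of 0, print-tip loess, marker lei0079 left out, 5 components as covariates, the bird of the other reference label left out, or adjustment within each marker. It fell to 0, as did the count of block F, with no background correction, the authors' values, no filter on dim probes, the first listed allele as paternal, own genotype only, a genotyping error of 0.05, number series as covariate, inverse normal ranks, and the authors' values with 5 components. The authors' table does not hold RIGG01025, and testing 20460 probes without the filter left its difference at -0.40. There it ranked 2, with a limma p of 5.27e-07. A probe that the filter had removed had the smallest limma p, 1.74e-07, with an adjusted p of 0.103. With own genotype only, 30 birds were settled at huj0006, and the difference of RIGG01025 was -0.41. For the other settings the cause was not tested. Where it was measured on the log2 scale, the difference of RIGG01025 lay between -0.47 and -0.25, always negative, with adjusted p from 0.0102 to 1.00. At index marker huj0006 the count fell to 0 with the authors' values, alone or with 5 components, with the first listed allele, and with inverse normal ranks. No background correction with 5 components gave 2 probes over all markers, 1 of them in block I. The authors' values with 5 components gave 1 probe at index marker mcw0083. Aquantile left every log ratio as it was and so tests nothing. The other 8 blocks and 8 other index markers stayed at 0 in 245 of 247 alternatives, Aquantile aside. With adjustment within each of the 29 markers the count was 1 in the main setting. It was 40 with own genotype only, where as few as 9 birds were settled at a marker (seq0352). It was 5 with the authors' values with 5 components. It was 2 each without the filter, with the number series, and with 5 components, alone or with no background correction. The count fell to 0 with the authors' values, the first listed allele as paternal and inverse normal ranks, and was 1 in the remaining settings.

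The median SD between birds was 0.206 with no background correction, 0.261 with an offset of 0 and 0.240 in the authors' values, outside or at the edge of its bootstrap interval, and within it under the remaining alternatives. The cause was not tested. A median foreground of 259 over a background of 228 limits what dim probes can show. The slide or scan batch, the averaging of probes per gene, and the alternatives of gene lists and chromosomes were not run, because the files used here give neither batches nor gene names, and own genotype only gave no value at 1 index marker.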

Other observations

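Some tests in this part were chosen before their own result was seen. They include the reassignments of genotypes counted over all markers, at huj0006 and at mcw0020. The scans in the planned settings, such as that with the number series as a covariate, were also chosen before. So were the share at mcw0020 with components as covariates, the comparison of components over all probes, and the correlation with neighbouring spots. The patterns that these tests address had been seen by then. Markers huj0006 and mcw0020, and the probes set against neighbouring spots, were picked from these data. The other tests here were chosen only after the result was seen, and the comparison of components over shared probes and birds is one of them.

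Whether the single linked probe stands out from chance was tested by reassigning whole genotypes among birds. Of 100 draws, the real one included, 3 gave 1 or more linked probes over all markers, a share under 0.05, where the real count was 1 and the highest of the other draws 1111. With adjustment within a marker, chance was not excluded: 22 of 100 draws gave 1 or more probes at one of the 9 index markers, the highest of the others being 810. At huj0006 alone 3 draws did, the highest of the others reaching 8, but that is the marker where the probe lies and the count makes no allowance for the other 8. In the draw with 1111 probes a reassigned marker correlated with one of the first 5 components at 0.695 in size, the largest of all draws, against a median of 0.402 and 0.475 for the real genotypes. The linked probe is still a narrow call, lost when the number series is a covariate (adjusted p 0.146), although the difference was then -0.41 against -0.40 without it. The excess of small p-values at mcw0020 was not unusual, since 79 of 100 draws had as many at their best marker, the highest reaching 2768 probes. With the first 5 components as covariates the share there was 4.6% in place of 10.9%, and 3.6% in place of 10.2% with no background correction, but in the authors' values it went the other way, to 14.1% from 8.2%.

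RIGG11960, singled out after its values were seen, was lower in birds with allele 7 than with allele 3 of adl0326 in block I, at -0.12 ± 0.29 (SD, n = 18) against 0.17 ± 0.19 (SD, n = 17). Its limma adjusted p over all markers was 1.00, and among the settings run it passed only with no background correction and 5 components as covariates, at 0.0415. It had the smallest p of all probes in the authors' values, 1.09e-05, with an adjusted p of 1.00.

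The main axis of expression, which RIGG02581 follows, is a pattern worth a closer look. The log ratio of the median foregrounds explained an r squared of 0.0956 (Pearson's r 0.309, permutation p 0.0441, adjusted p over 3 measures 0.123). Spearman's rho was 0.252 (permutation p 0.105). Without the 2 farthest birds Pearson's r was 0.166, and within series it was 0.725, 0.121 and 0.379 for 41xx, 56xx to 57xx and 64xx. These foregrounds lay near background (median 259 over 228 in the bird channel). The measure therefore cannot decide whether unequal signal of the channels was a cause. The share of flagged spots (r squared 0.00364) and the number series (r squared 0.0958) explained little too, and the share of usable spots had r 0.269 (permutation p 0.0819), with 0.507 within 64xx. Over all probes of the authors' table its axis correlated with this one at only 0.775 in size, but over the shared probes and birds it reached 0.9946 and that without background correction 0.9949, which argues against the background correction; normalization within arrays stays open, since how the authors normalized is not known. No paternal allele was linked to it, with a smallest adjusted permutation p of 0.786 over 29 markers, which does not exclude a small effect or an untyped region, and feeding state within the stated minimum of 4 h is an untested hypothesis.

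A pair of bright probes, picked by eye from those with the largest gaps between neighbouring birds, had values in 2 separate sets. RIGG14021 was between -0.70 and -0.15 in 28 birds and between 0.32 and 0.93 in 15, and RIGG12105 between -1.62 and -0.52 in 14 and between 0.07 and 0.51 in 29. Against normal samples, with at least 5 birds on each side, 4 of 10000 had a gap as large as RIGG14021, the smaller one, and 1 as large as RIGG12105, which over 5763 probes does not exclude chance for either. Gaps were more frequent than in normal samples as a whole, with 23 probes beyond a bound that 5.8 were expected to pass. RIGG14021 and RIGG12105 ranked 9 and 6, and 8 of the 10 largest gaps cut off only the 5 lowest birds. With at least 10 birds on each side these probes ranked 2 and 1. Their gaps were then 0.948 and 1.02 SD, and 0 of 10000 normal samples had one as large (at most 0.739 SD). That requirement was set after the values were seen, so chance is not excluded by it either. A fault shared by the surrounding spots was looked for in their 8 nearest spots, taken whether or not they were bright enough to be tested. The median correlation was 0.00 for RIGG14021 (-0.06 to 0.26). For RIGG12105 it was 0.0990 in size, negative (-0.50 to 0.64, so single neighbours did follow or oppose it). Dim neighbours may fail to show a shared fault, so these values cannot exclude one. No paternal allele was linked to either, with a smallest adjusted p of 1 over 58 tests. At the 3 markers that show maternal alleles, RIGG14021 had its smallest limma p at adl0314 (0.00296, adjusted over 6 tests 0.0177). With the number series as a covariate it was 0.00603 unadjusted. RIGG12105 had none under 0.356. These p-values treat the birds as independent, and no dam was fitted. Birds with the same maternal allele may share a dam, so the allele cannot be told apart from a difference between dams. The low set of RIGG12105 held 7 of 11 birds numbered 41xx, 0 of 16 numbered 56xx to 57xx, 5 of 12 numbered 64xx and 2 of 4 numbered 65xx (limma p over series 0.0103, adjusted over both probes 0.0205), so a difference between series stays open for it, and what the series stand for is not stated in the labels.

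Between the 4 series of animal numbers, 22 probes differed (limma, Benjamini-Hochberg), and 3 of 100 draws gave as many, the highest of the others being 377; without the 4 birds numbered 65xx the count was 0, with 12.1% of the probes at an unadjusted p under 0.05. At the 3 markers where the sire carried 1 allele, and the other allele of each bird is maternal, 0 probes passed with limma, and 13.3, 10.5 and 7.1% had an unadjusted p under 0.05 at lei0101, adl0314 and lei0088. Reassigned birds gave shares as large in 9, 9 and 21 of 100 draws, with medians of 3.9, 3.5 and 3.3%, so these shares lie within the range of chance.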
